A study of Homo sapiens with 6 samples.

How the data were processed

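The series holds 6 libraries of total RNA from BEAS-2B cells, 3 kept in 2.0 µM cadmium and 3 at 0.0 µM for 20 weeks. Per the labels' protocols, exposure began 6 hours after seeding, cells were subcultured every 3 days, ribosomal RNA was removed, linear RNA was digested with RNase R, and libraries were made with dUTP in the second strand, which keeps the strand. RNase R depletes linear RNA to a degree that can differ between libraries, so junction reads give the amounts of circRNAs relative to each other and not to their linear transcripts. Samples were assigned to groups from the treatment given in the labels, and replicate numbers from the titles.

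The authors' deposited counts are whole numbers of back-splice junction reads per circRNA and library, as the column names in the files say. The table holds no value of 1, and each of its 9857 circRNAs is above 0 in all 3 libraries of at least 1 group, so circRNAs seen in fewer libraries are not analysed here. The deposited TPM values equal the count as a share of the library total, scaled to TPM with no length term. They were used only in 1 alternative. The authors' deposited comparison holds group means of normalised reads (a signal with no replicates), log2 fold changes and p-values, unadjusted and adjusted. It was read only for the comparison named as theirs. The authors' annotation table gives each circRNA's position, class, host gene, junction reads and the reads of the locus that do not cross the junction. The sources used here do not say how the latter were counted. Per the submitters' processing notes, Bowtie2 2.2.8, Bowtie, DESeq 1.10.1 and hg19 were used, with no role given. The circRNA caller is not given in the sources used here. The notes name hg19, but the deposited positions follow GRCh38: 98.0% of exonic circRNA starts and 98.1% of ends lie on exon bounds of GENCODE 29 on GRCh38, and positions are given in that build, counted from 1. Exon numbers come from a GENCODE 29 transcript with both ends on its exon bounds, found for 8906 of 9400 exonic circRNAs. Of 12 identifiers with more than 1 annotation entry, 2 had different reads in their entries (hsa_circ_0006922 and hsa_circ_0002069), and the counts of the count table were used.

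Library totals ran from 133185 to 225769 junction reads. Pairs of libraries of a group differed by more than counting noise (chi-square per degree of freedom 1.59 to 2.49), so none was taken for a copy of another. That does not show that they are separate cultures, since repeat preparations would also exceed counting noise. Reads without molecular identifiers are not independent molecules.

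The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust fitting, filterByExpr (minimum count 5, minimum total 15) and a Benjamini-Hochberg adjusted p under 0.05. It left 6182 circRNAs. Counts summed over the circRNAs of 1 host gene were tested in the same way (3008 genes), leaving out 240 circRNAs with more than 1 host gene and 74 with none. Gene lists and chromosomes were tested on the log-CPM of host genes (prior count 2) with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists needed 5 tested hosts and chromosomes 10. Depth, detection and class shares were compared by two-sided exact permutation tests. Values in CPM use the TMM library sizes and are given as mean ± SD. The standard error (SE) of an edgeR log2 fold change was worked back from the test. It is the size of the log2 fold change over the square root of the F statistic.

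The design, the lists, the alternatives and the rule for named circRNAs were fixed before the data were examined. The rule takes the 8 that rose and the 8 that fell with the smallest p among those past the threshold with groups that do not overlap, filled in order of p with others not passing. It adds the 6 with the highest mean CPM, up to 3 called host genes per list, every tested circRNA of the 2 followed-up hosts, and the 8 most abundant from hosts of well-studied circRNAs. Other names, the members given as examples of lists among them, were chosen after the values were seen. Values of some members of the gene lists are not reported here.

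Alternatives were other size factors, library totals alone, other filters, DESeq2 1.42.0, limma on log2(TPM + 1), the replicate number as a block, a 2-fold minimum, single circRNAs in place of host genes as members of lists and chromosomes, and leaving out each library in turn. Chosen after seeing the data were the log2 ratio of junction to non-junction reads as a covariate, leaving out control replicates 1 and 3 (which leaves 1 control library, assumed to vary like the cadmium libraries), the other entry of the 2 identifiers, removal of the GC trend of host genes, and leaving out circRNAs with a 0 where 10 or more reads were implied. All 10 splits of the 6 libraries into 3 and 3 were also tested.

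The tests were tried on simulated counts with the means and totals of the real libraries. For the circRNA comparison (6046 circRNAs in that step), edgeR recovered 0 of 62 changed by 1.5-fold, 11 of 61 (18.0%) changed by 2-fold and 40 of 53 (75.5%) changed by 4-fold, with 3 false calls among 5870. For the host gene comparison (2961 genes in that step) it recovered 7 of 64, 38 of 64 (59.4%) and 58 of 62 (93.5%) at these folds, with 9 false calls among 2771. With no gene changed it made 2 calls among 6027 circRNAs and 1 among 2961 host genes. With 2 chromosomes shifted by 0.3 on the log2 scale, camera called both, and with 2 shifted by 0.15 it called 1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.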

Results

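Circular RNAs were sequenced in BEAS-2B cells, an immortalised line of human bronchial epithelial cells. Circular RNAs (circRNAs) are closed transcripts in which the end of a downstream exon is joined to the start of an upstream exon, and each is counted by the reads that cross this back-splice junction. Cells kept in 2.0 µM cadmium for 20 weeks (3 libraries) were compared with cells kept at 0.0 µM (3 libraries). Ribosomal RNA was removed and linear RNA was digested with RNase R before stranded libraries were made. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The question addressed is which circRNAs differ after long cadmium exposure.

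The files list 9857 circRNAs, of which 9400 are exonic, 383 intronic and 74 intergenic. A single host gene was assigned to 9543 of them, from 3742 genes in all, and TRIO gave the most, 26. The median spliced length was 380 bases. Junction reads numbered 225769, 137919 and 165352 in control replicates 1 to 3 and 133185, 135686 and 160248 in cadmium replicates 1 to 3. The median was 7 reads per circRNA and library, so most single circRNAs were counted with low precision.

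Fewer circRNAs were detected in each cadmium library than in each control library. The mean was 8755 ± 91.1 (SD, n = 3) with cadmium and 9176 ± 246 (SD, n = 3) in controls, a difference of -420.7 (two-sided exact permutation p = 0.1). With 3 libraries against 3, 0.1 is the smallest p this test can give. Thinned to 133185 reads each, the libraries held 8747 ± 79.3 and 9112 ± 168 circRNAs (SD, n = 3 each, exact permutation p = 0.1). Mean junction reads were 143040 ± 14955 with cadmium and 176347 ± 44945 in controls (SD, n = 3 each, exact permutation p = 0.2). Listed above 0 in all 3 libraries of 1 group and at 0 in the other were 212 circRNAs for control and 93 for cadmium. At equal depth, with 2 or more reads as the bound, these numbers were 151 and 142. Which circRNAs are listed at all was decided at full depth, which was higher on average in controls, and thinning does not undo that. A listed 0 is not always absence, because 94 zeros stand in libraries where the other libraries of the group imply 10 or more reads.

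Exonic circRNAs took 96.5% ± 0.121 of junction reads with cadmium and 96.3% ± 0.0490 in controls (SD, n = 3 each, exact permutation p = 0.3). Intronic circRNAs took 3.00% ± 0.122 and 3.15% ± 0.0840 (exact permutation p = 0.3), and intergenic circRNAs 0.538% ± 0.00385 and 0.530% ± 0.0576 (exact permutation p = 1.0). By spliced length, circRNAs of up to 300 bases took 16.4% ± 1.24 with cadmium and 16.5% ± 0.703 in controls (exact permutation p = 1.0). Those over 300 and up to 500 bases took 53.7% ± 3.03 and 52.8% ± 1.83 (exact permutation p = 0.6), and longer ones 29.9% ± 1.84 and 30.7% ± 2.41 (exact permutation p = 0.5). For none of these classes was the smallest possible p reached. A weighted share of junction reads was taken over the circRNAs with non-junction reads given in every library. It is the doubled number of junction reads over the sum of that doubled number and the non-junction reads. This weighted share was 46.1%, 29.2% and 48.9% in control replicates 1 to 3 and 30.0%, 31.7% and 30.3% in cadmium replicates 1 to 3 (exact permutation p = 0.4). Control replicates 1 and 3 therefore stood apart from the other 4 libraries in this measure.

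**Figure D1:**
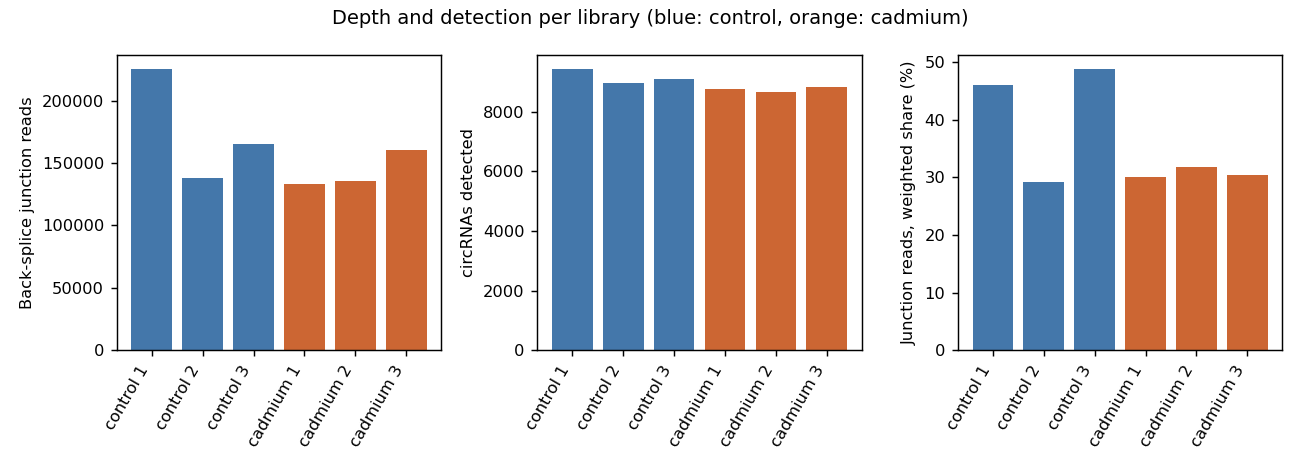
Junction reads, detected circRNAs and the weighted share of junction reads (%) in each of the 6 libraries, with control in blue and cadmium in orange. Detected circRNAs run from 8662 to 8844 with cadmium and from 8973 to 9449 in controls, and control replicates 1 and 3 have weighted junction shares of 46.1% and 48.9%.

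In cadmium-exposed cells 5 circRNAs fell and 0 rose among 6182 tested. A pair of them came from SPAG16, which encodes a protein of the central apparatus of motile cilia. The first, hsa_circ_0058040 (chromosome 2, 213310059 to 213375119, GRCh38, exons 4 to 9 of 16), fell from 521.6 ± 105 to 135 ± 6.77 CPM (SD, n = 3 each, log2 fold change -1.94, SE 0.24, edgeR adjusted p = 0.00543). The second, hsa_circ_0004664, starts at the same base of SPAG16 and ends after exon 8 at 213364145. It fell from 211 ± 44.7 to 37.2 ± 7.76 CPM (SD, n = 3 each, log2 fold change -2.50, SE 0.36, edgeR adjusted p = 0.0128). From ZDBF2, an imprinted zinc finger gene on the same chromosome arm, hsa_circ_0002141 (206279540 to 206297373, exons 2 to 5 of 6) fell from 3604 ± 128 to 1804 ± 212 CPM (SD, n = 3 each, log2 fold change -1.0, SE 0.13, edgeR adjusted p = 0.00703).

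The other 2 calls lay on chromosomes 3 and 18. The intronic circRNA hsa_circ_0002134 of PTPRG, a receptor-type tyrosine phosphatase gene (chromosome 3, 61622463 to 61623555), fell from 1407 ± 132 to 681 ± 70.8 CPM (SD, n = 3 each, log2 fold change -1.05, SE 0.16, edgeR adjusted p = 0.0128). From VAPA, which encodes a membrane protein of the endoplasmic reticulum, hsa_circ_0006990 (chromosome 18, 9931810 to 9937066, exons 2 to 4 of 7) fell from 2632 ± 273 to 1455 ± 49.5 CPM (SD, n = 3 each, log2 fold change -0.85, SE 0.13, edgeR adjusted p = 0.0201). For all 5 circRNAs each of the 3 cadmium libraries lay below each of the 3 controls. Such separation of the groups was seen for 946 of 6182 circRNAs (15.3%), where chance gives 10% for circRNAs picked without regard to group. Only circRNAs above 0 in all 3 libraries of a group are listed, which can favour separated groups. The share that chance gives here is therefore not known. At an unadjusted p under 0.05, 267 circRNAs were higher and 240 lower by edgeR. At an adjusted p under 0.05, DESeq2 and limma each gave 5 that fell and 0 that rose. The edgeR count at this adjusted threshold was 0 without control replicate 1, 13 without control replicate 2 (7 rose and 6 fell), 1 without control replicate 3, 3 without cadmium replicate 2 and 9 without cadmium replicate 3. The SPAG16 circRNA hsa_circ_0058040 lost its call without control replicate 1 (edgeR adjusted p = 0.0839), the ZDBF2 circRNA also without control replicate 3 (up to 0.213), hsa_circ_0004664 and the PTPRG circRNA also without cadmium replicate 2 (up to 0.278), and the VAPA circRNA in 5 of the 6 fits.

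**Figure D2:**
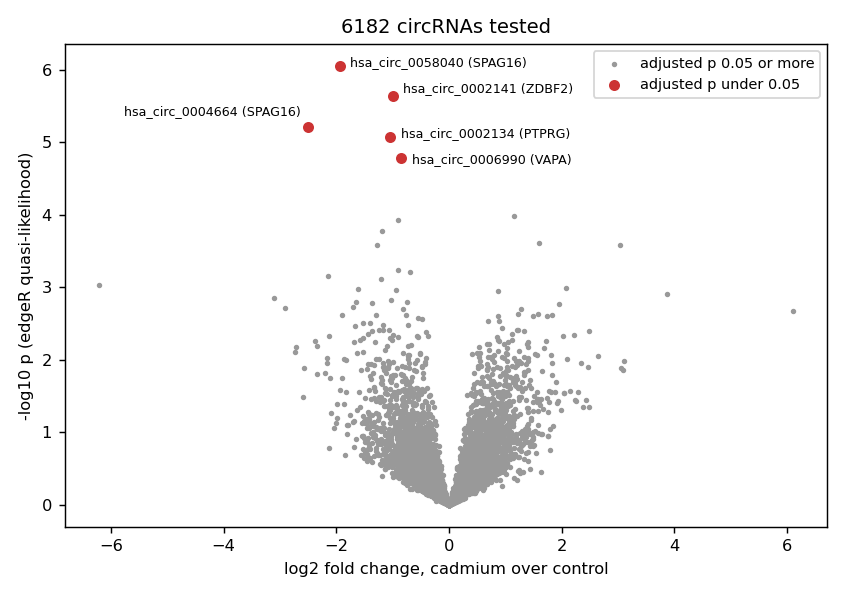
Log2 fold change (cadmium over control) of 6182 circRNAs against -log10 of the edgeR p-value, with each circRNA as a point and those past an adjusted p of 0.05 in red. All 5 red points lie to the left, with log2 fold changes from -2.50 to -0.85.

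Higher with cadmium but not past the threshold were circRNAs of genes with different roles. The circRNA novel_circ_0024095 of GTF3C2, which encodes a subunit of a general transcription factor of RNA polymerase III (chromosome 2, 27350314 to 27350632, exon 2), stood at 283 ± 44.0 and 626 ± 139 CPM in control and cadmium (SD, n = 3 each, log2 fold change 1.16, edgeR adjusted p = 0.104). For hsa_circ_0006847 of ASPHD1 (chromosome 16, 29904852 to 29905959) the log2 fold change was 1.61, and for hsa_circ_0029584 of CHFR, a mitotic checkpoint ubiquitin ligase gene (chromosome 12, 132844027 to 132848724), it was 3.04 (edgeR adjusted p = 0.148 for both). The CHFR circRNA stood at 13.5 ± 11.9 and 127 ± 70.8 CPM (SD, n = 3 each), and 0 of its reads were listed in control replicate 2. Then followed hsa_circ_0038773 of the exportin gene XPO6 (chromosome 16, 28101458 to 28101945, log2 fold change 0.87) and novel_circ_0015213 of SIPA1L3 (chromosome 19, 38130498 to 38130772, log2 fold change 2.07), both with an edgeR adjusted p of 0.348. With an edgeR adjusted p of 0.378 came hsa_circ_0059802 of the DNA methyltransferase gene DNMT3B (chromosome 20, 32791601 to 32792770, log2 fold change 1.96) and hsa_circ_0075835 of MRS2, a mitochondrial magnesium channel gene (chromosome 6, 24416397 to 24418578, log2 fold change 1.28).

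Lower with cadmium but not past the threshold was novel_circ_0016395 of the antisense transcript FLG-AS1 (chromosome 1, 152314906 to 152335439), at 664 ± 18.9 and 355 ± 13 CPM in control and cadmium (SD, n = 3 each, log2 fold change -0.90, edgeR adjusted p = 0.104). The ZCCHC2 circRNA hsa_circ_0000854 (chromosome 18, 62539681 to 62550460) had a log2 fold change of -1.18 (edgeR adjusted p = 0.129). For hsa_circ_0001258 of PPP6R2, which encodes a regulatory subunit of protein phosphatase 6 (chromosome 22, 50372020 to 50394135), it was -1.28 (edgeR adjusted p = 0.148).

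None of the 6 most abundant circRNAs passed the test. The highest was hsa_circ_0001535 of FAM13B (chromosome 5, 137985257 to 137988315), at 8619 ± 273 CPM in controls and 8990 ± 2033 with cadmium (SD, n = 3 each). Its log2 fold change was 0.06 (edgeR adjusted p = 0.939), and its sign turned in 2 of the alternative fits. Next came novel_circ_0026364 of the collagen lysyl hydroxylase gene PLOD2 (chromosome 3, 146121112 to 146124229), at 8225 ± 804 and 6245 ± 543 CPM, with a log2 fold change of -0.40. For hsa_circ_0001355 of RSRC1 (chromosome 3, 158122103 to 158123991) it was -0.36 (edgeR adjusted p = 0.421 for both). For these 2 and for the CDYL circRNA hsa_circ_0008285, also among the 6 (log2 fold change -0.34), each cadmium library lay below each control (edgeR unadjusted p = 0.00416, 0.00461 and 0.0301).

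Among hosts of circRNAs that have often been studied, none of the 8 most abundant passed the test. Log2 fold changes were -0.17 for hsa_circ_0001900 of CAMSAP1 (chromosome 9, 135881633 to 135883078), -0.34 for hsa_circ_0008285 of CDYL (chromosome 6, 4891713 to 4892379) and -0.11 for hsa_circ_0001445 of SMARCA5 (chromosome 4, 143543509 to 143543972). They were -0.22 for hsa_circ_0001017 of XPO1 (chromosome 2, 61522611 to 61533903) and 0.47 for hsa_circ_0001821 of PVT1 (chromosome 8, 127890589 to 127890998). A pair of MAN1A2 circRNAs on chromosome 1, hsa_circ_0000118 (117402186 to 117420649) and hsa_circ_0000117 (117402186 to 117414831), had -0.02 and -0.26. The signs for CAMSAP1, SMARCA5, PVT1 and hsa_circ_0000118 turned in 1 or 2 alternative fits. For hsa_circ_0000284 of the kinase gene HIPK3 (chromosome 11, 33286413 to 33287511) 1153, 0 and 537 reads were listed in control replicates 1 to 3 and 948, 975 and 865 with cadmium, so 1 control library decides its fold change.

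Hosts of circRNAs followed up in published cadmium work on these cells were looked at as a list of 2 genes. That choice may have been made on these libraries, so their values are not independent evidence. For SHPRH, a ubiquitin ligase gene, hsa_circ_0001649 (chromosome 6, 145888020 to 145894977) stood at 111 ± 43.0 CPM in controls and 119 ± 49.8 with cadmium (SD, n = 3 each, log2 fold change 0.07, edgeR adjusted p = 0.974). Its sign turned in 3 of the alternative fits. For PUS7, a pseudouridine synthase gene on chromosome 7, hsa_circ_0008628 (105459168 to 105465414) had a log2 fold change of 0.32 (edgeR adjusted p = 0.820). The PUS7 circRNA hsa_circ_0081844 (105462621 to 105468463) had 0.23 (edgeR adjusted p = 0.906), with the opposite sign in 1 of the alternative fits. The third PUS7 circRNA, novel_circ_0034496 (105508115 to 105508544), had 2, 0 and 0 reads in control replicates 1 to 3 and 10, 6 and 12 with cadmium (edgeR adjusted p = 0.362), too few for a firm fold change. Summed over all circRNAs of a gene, PUS7 had 0.38 (edgeR adjusted p = 0.551) and SHPRH -0.18 (edgeR adjusted p = 0.821).

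When reads were summed per host gene, 6 of 3008 genes fell and 1 rose. SPAG16 fell from 1084 ± 89.1 to 307 ± 40.5 CPM (SD, n = 3 each, log2 fold change -1.82, SE 0.16, edgeR adjusted p = 5.77e-05), with 5 circRNAs in the sum. ZDBF2 fell from 3698 ± 171 to 1851 ± 248 CPM (log2 fold change -1.0, SE 0.12, edgeR adjusted p = 0.00137). PTPRG fell from 2067 ± 204 to 986 ± 122 CPM (log2 fold change -1.07, SE 0.14, edgeR adjusted p = 0.00151) and VAPA from 3060 ± 271 to 1762 ± 53.0 CPM (log2 fold change -0.80, SE 0.12, edgeR adjusted p = 0.00482). GTF3C2 rose from 289.8 ± 41.0 to 641 ± 141 CPM (log2 fold change 1.16, SE 0.21, edgeR adjusted p = 0.0343). PPP6R2 fell from 478 ± 113 to 196 ± 49.1 CPM (log2 fold change -1.31, SE 0.25) and ZCCHC2 from 489 ± 97.6 to 214 ± 43.6 CPM (log2 fold change -1.19, SE 0.23), both with an edgeR adjusted p of 0.0494. For ZDBF2, GTF3C2 and ZCCHC2 the sum holds a single circRNA. Those of GTF3C2 and ZCCHC2 are the circRNAs that did not pass among the 6182 (edgeR adjusted p = 0.104 and 0.129), and the sums add no reads to them.

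The remaining SPAG16 circRNAs did not pass the test one by one. The log2 fold change was -2.15 for hsa_circ_0005760 (edgeR adjusted p = 0.307), -1.61 for hsa_circ_0058039 (edgeR adjusted p = 0.348) and -0.22 for novel_circ_0023492 (edgeR adjusted p = 0.937). Of the host genes, 581 of 3008 (19.3%) had groups that did not overlap. Chance gives 10% for genes picked without regard to group, and the listing of circRNAs by group can raise this. At an unadjusted p under 0.05 by edgeR, 177 were higher and 198 lower. SPAG16, ZDBF2 and PTPRG kept their calls in all 6 fits that left out a library, VAPA (edgeR adjusted p up to 0.0944) and GTF3C2 (up to 0.354) in 3, and PPP6R2 (up to 0.354) and ZCCHC2 (up to 0.288) in 1. The count was 3 without control replicate 1, 10 without control replicate 2 (5 rose and 5 fell), 4 without cadmium replicate 1, 3 without cadmium replicate 2 and 13 without cadmium replicate 3.

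**Figure D3:**
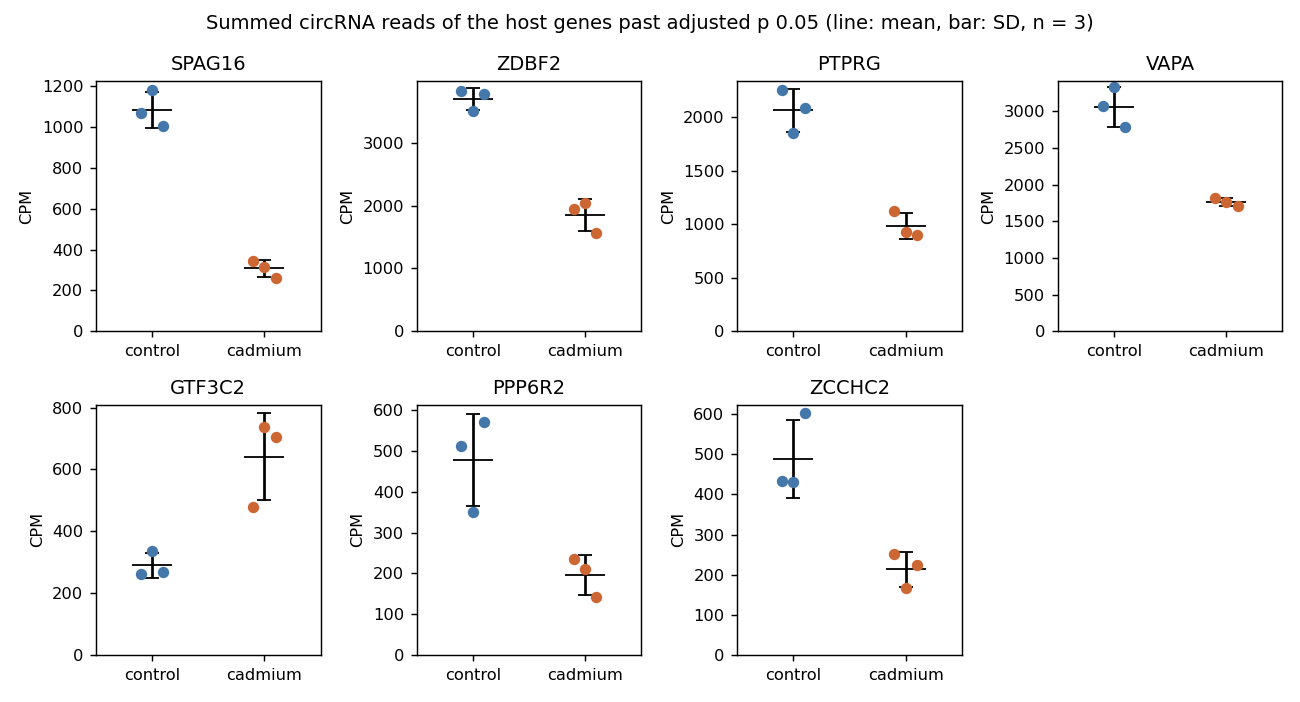
Summed circRNA reads (CPM) of the 7 host genes past an adjusted p of 0.05 in the 3 control and 3 cadmium libraries, with points for libraries, lines for means and bars for SD. SPAG16 lies between 263 and 342 CPM with cadmium and between 1003 and 1180 CPM in controls, and GTF3C2 alone lies higher with cadmium.

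None of 14 gene lists with 5 or more tested host genes was shifted as a whole by camera, either with the preset correlation or with an estimated one, and 0 had an unadjusted p under 0.05. With the preset correlation the lowest p was that of fibroblast and mesenchymal markers (8 hosts, median log2 fold change -0.37, camera adjusted p = 0.502, adjusted p = 0.683 with an estimated correlation), and with the estimated correlation that of the adhesion list. No list held a member past the threshold over all host genes, and adjusted over the list alone 1 fell in each of 2 lists. These were VPS13C, a lipid transfer protein gene, in autophagy and lysosome (30 hosts, log2 fold change -1.03) and the zinc finger gene BNC2 among fibroblast and mesenchymal markers (log2 fold change -0.99). The fry test, which asks whether the genes of a list move one way without comparing them with other genes, gave 1 of 14 lists past the threshold, and 11 when changes in either direction were counted together. The list that moved one way was adhesion, matrix and epithelial-mesenchymal genes (24 hosts, 16 lower and 8 higher, median log2 fold change -0.21, limma fry adjusted p = 0.0165). The list members named as examples, none of which passed the test, were chosen after their values were seen. In the adhesion list ADAM10, a membrane protease gene, had a log2 fold change of -1.05 and PTK2, the gene of focal adhesion kinase, -0.22, while the laminin gene LAMC1 had 1.03. At an unadjusted p under 0.05, 0 members were higher and 2 lower in the adhesion list, 0 and 4 in autophagy and lysosome, and 0 and 1 among fibroblast and mesenchymal markers.

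In metal handling and oxidative stress (19 hosts, median log2 fold change -0.04, 0 rose and 0 fell), SLC39A8, a zinc and cadmium importer gene, had a log2 fold change of -1.06 (edgeR adjusted p = 0.204) and the zinc transporter gene SLC30A5 0.97, with 0 members higher and 2 lower at an unadjusted p under 0.05. In DNA repair and damage signalling (63 hosts, median 0.11), PARP4 had 1.38, the DNA ligase gene LIG1 1.29 (edgeR adjusted p = 0.186 for both) and the Fanconi anaemia gene FANCA 1.08, with 6 members higher and 1 lower at an unadjusted p under 0.05. In chromatin and histone modifiers (86 hosts, median -0.10), DNMT3B had 1.05, the histone deacetylase gene HDAC8 0.81, the histone methyltransferase gene ASH1L -0.41 and the chromatin remodeller gene CHD7 -0.53, with 3 members higher and 5 lower at an unadjusted p under 0.05. In MAPK, receptor kinase and PI3K signalling (52 hosts, median -0.04), RICTOR, which encodes a subunit of an mTOR complex, had -0.52, RASA2, a Ras GTPase-activating protein gene, -0.58 and the protein kinase C gene PRKCI 0.89, with 2 members higher and 4 lower at an unadjusted p under 0.05. In TGF-beta, Wnt and Hippo signalling (36 hosts, 24 lower and 12 higher, median -0.15), SMAD2 had -0.61, LATS1 -0.96 and TEAD4 1.57, with 4 members higher and 5 lower at an unadjusted p under 0.05.

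Among ubiquitin ligases and deubiquitinases (79 hosts, median log2 fold change -0.04), MIB1 had -0.42 and CBL 0.93, with 1 member higher and 7 lower at an unadjusted p under 0.05. In cell cycle and DNA replication (67 hosts, median 0.01, mean -0.03), the cohesin gene STAG1 had -0.57 and the kinetochore gene SKA3 0.45, with 4 members higher and 6 lower at an unadjusted p under 0.05, and the camera direction was that of the mean. In apoptosis and cell stress (24 hosts, median 0.02) RIPK1 had 0.69 and CASP8AP2 -0.83, with 4 members higher and 1 lower at an unadjusted p under 0.05. In splicing and RNA-binding proteins (49 hosts, median 0.04) these were 1 and 1, RBM6 with 0.47 and DDX17 with -0.66. In centrosome and cilium (35 hosts, median -0.10) they were 2 and 4, with 1.41 for CEP78 and -0.44 for TTBK2. For hosts of well-studied circRNAs (58 hosts) the median was -0.09, with 3 members higher and 9 lower at an unadjusted p under 0.05. Lists of markers of other cell types held too few tested hosts for a test: 2 for ciliated and secretory cells, 1 for alveolar cells, 1 for blood and immune cells, and 0 each for basal and endothelial cells.

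By chromosome, host genes of chromosomes 18 and 22 were lower and those of chromosomes 16 and 19 higher in the cadmium libraries, each relative to all other host genes, by camera with the preset correlation. With an estimated correlation 0 of 23 chromosomes passed (adjusted p = 0.176 for chromosome 18, adjusted p = 0.304 for 19, adjusted p = 0.203 for 16 and adjusted p = 0.291 for 22, each with an estimated correlation). That estimate was below the preset 0.01 for chromosomes 18 (-0.0085) and 16 (0.0013), and above it for 19 (0.081) and 22 (0.027). A higher correlation therefore does not account for the lost calls of 18 and 16. On chromosome 18, 53 of 70 hosts were lower (median log2 fold change -0.27, camera adjusted p = 0.00286), VAPA and ZCCHC2 among them. On chromosome 22, 37 of 54 hosts were lower (median -0.29, camera adjusted p = 0.0392), PPP6R2 among them. On chromosome 19, 87 of 128 hosts were higher (median 0.22, camera adjusted p = 0.00466), and on chromosome 16, 78 of 119 (median 0.18, camera adjusted p = 0.0333). Chromosome 18 passed in all 6 fits that left out a library, while 18 and 19 alone passed without control replicate 3, without cadmium replicate 1 and without control replicates 1 and 3 together, and 18 alone without cadmium replicate 3. The joint removal leaves 1 control library, which is assumed to vary like the cadmium libraries. With single circRNAs in place of host genes as members, 18, 19 and 22 passed and 16 did not (camera adjusted p = 0.0504). Chromosome 19 did not pass without control replicate 2 (camera adjusted p = 0.134), nor did 16 and 22 without control replicate 1 (camera adjusted p = 0.227 and 0.188). Chromosome 13 (66 hosts, median 0.16, camera adjusted p = 0.0615) passed without control replicate 1, control replicate 2 or cadmium replicate 2. With the GC trend of the host genes removed, which like the joint removal was tried after the data were seen, chromosomes 16 and 19 did not pass (camera adjusted p = 0.212 for both) and 13 (camera adjusted p = 0.0288), 18 and 22 did (camera adjusted p = 0.00437 for both). By fry, which does not compare a chromosome with other genes, 6 of 23 passed, namely 2, 4, 14, 16, 17 and 18, and 19 and 22 did not (limma fry adjusted p = 0.174 and 0.107).

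**Figure D4:**
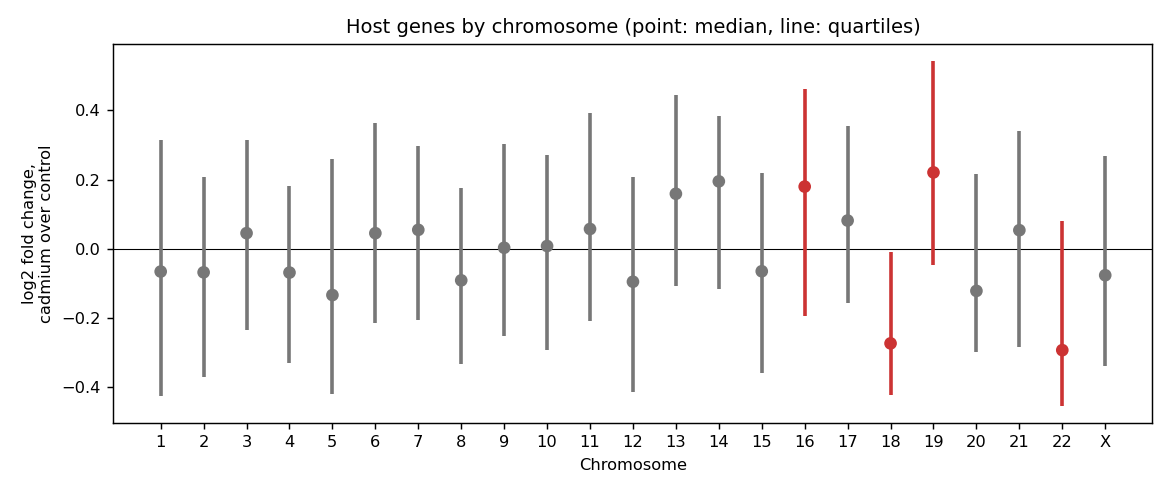
Median (point) and quartiles (line) of the log2 fold change, cadmium over control, of host genes on each of 23 chromosomes, with those past an adjusted p of 0.05 by camera in red. Chromosomes 18 and 22 have medians of -0.27 and -0.29, and chromosomes 16 and 19 of 0.18 and 0.22.

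SPAG16 and ZDBF2, the host genes with the 2 smallest p-values, lie 7.01 Mb apart on the long arm of chromosome 2. Between 200 and 220 Mb, 19 other host genes were tested, and 15 of them had log2 fold changes below 0 (median -0.37). None of the 19 passed the test. PARD3B, a cell polarity gene, had -0.78 (edgeR adjusted p = 0.238), the DNA repair gene XRCC5 -0.37 (edgeR adjusted p = 0.614) and ARPC2 1.49 (edgeR adjusted p = 0.339). Nearer to the pair, NDUFS1 beside ZDBF2 had -0.05 (SE 0.20), PIKFYVE between ZDBF2 and SPAG16 0.01 (SE 0.23), CREB1, also between them, -0.73 (SE 0.42) and BARD1 -0.27 (SE 0.18). This region and the genes named in it were chosen after the values were seen.

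**Figure D5:**
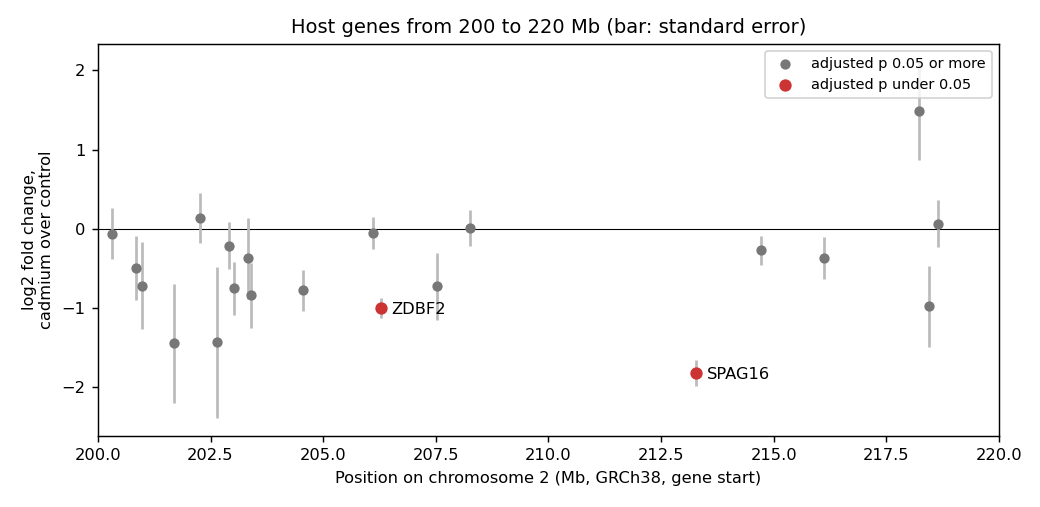
Log2 fold change (cadmium over control) of 21 host genes against gene start between 200 and 220 Mb of chromosome 2 (GRCh38), with bars for the standard error. SPAG16 at -1.82 and ZDBF2 at -1.0, in red, are past an adjusted p of 0.05.

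In the authors' deposited table of the same contrast, 506 circRNAs have an unadjusted p under 0.05, 235 higher and 271 lower with cadmium. An adjusted p is given there for 3939 circRNAs and lies under 0.05 for 6, namely the 5 called by edgeR and, as the only higher one, hsa_circ_0029584 of CHFR. In the authors' deposited table the CHFR circRNA has an adjusted p of 0.0311 and a log2 fold change of 1.80, which is below the log2 of the ratio of the group means given beside it (19.4 normalised reads with cadmium and 2.08 in controls). How it was made is not given in the sources used here. Over the 6182 circRNAs tested in both, the sign in the authors' deposited table equalled that of edgeR for 98.7%. At an unadjusted p under 0.05, 232 circRNAs passed in both, out of 235 that passed in the authors' deposited table and were tested by edgeR. By edgeR 507 passed at that threshold, so most of these did not pass in the authors' deposited table. The rest of the authors' 506 were not tested by edgeR.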

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

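The tests on the 5 circRNAs were chosen only after the result was seen. For the chromosomes, bounds for the splits, the first GC test, the ratio test and the neighbour test were written before these tests were run. The GC trend and the ratio themselves were taken up only after the data were seen. The division of the GC test and of the ratio test into 2 parts each was made after their results. Groups of 3 are too small to be searched for single outlying libraries.

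The 5 circRNAs that fell came from SPAG16, ZDBF2, PTPRG and VAPA. With the ratio of junction to non-junction reads as a covariate, they had from 89.1% to 117% of their log2 fold changes. This covariate sets control replicates 1 and 3 apart, so these estimates rest largely on control replicate 2. They argue against the different ratio of control replicates 1 and 3 as the whole cause only as far as 1 control library can. Of the 5 calls, that of the SPAG16 circRNA hsa_circ_0058040 stayed (log2 fold change -1.94 with SE 0.24 before and -2.19 with SE 0.27 after, edgeR adjusted p = 0.0131). The others ended as standard errors grew, for ZDBF2 from 0.13 to 0.17 (log2 fold change -0.95 after), PTPRG from 0.16 to 0.21 (-0.96), VAPA from 0.13 to 0.17 (-0.996) and hsa_circ_0004664 from 0.36 to 0.46 (-2.23). Less circle formation with no change in the other reads of the locus may be a cause. But the non-junction reads of the 5 circRNAs had a median log2 fold change of -1.49 (from -1.94 to -1.03) relative to all loci. The values -1.49 and -1.94 are both of SPAG16, whose called circRNAs overlap, so these are not 5 separate loci. That cause stays open because the sources used here do not say whether these reads lie inside the circle. The 10 splits of the libraries are too few for a share under 0.05 (real split 5 circRNAs, highest other 0, 1 of 10 with as many), and an effect of cadmium itself stays open and was not tested apart from other differences between the cultures.

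For the host genes of chromosomes 16, 18, 19 and 22, an outcome for GC content as the cause was written before the test. It was that no more than 50% stay past the threshold without the GC trend, and it was met, since 2 of 4 stayed. These were chromosomes 18 and 22, with medians in log-CPM of -0.28 and -0.25 before and -0.22 and -0.27 after, which, in a division made afterwards, argues against GC content as their whole cause. For chromosomes 16 and 19, 0 stayed past the threshold as the medians shrank (0.17 and 0.18 before, quartiles -0.17 to 0.44 and -0.04 to 0.47, and 0.12 and 0.08 after, quartiles -0.21 to 0.43 and -0.10 to 0.37), so GC content of the host genes may account for a part. The different ratio of junction to non-junction reads in control replicates 1 and 3 had a test whose bound was written before it was run. That test left 2 of 4, chromosomes 18 and 19, with at least 50% of their median against control replicate 2 alone. With the ratio as a covariate these 2 also stayed past the threshold (camera adjusted p = 0.00698 and 0.000431, median log2 fold changes -0.27 and 0.22 before and -0.32 and 0.37 after). That fit too rests largely on control replicate 2. Both tests therefore argue against the ratio as the whole cause for 18 and 19 only as far as 1 control library can. For 16 and 22, of which 0 stayed (camera adjusted p = 0.365 and 0.469, medians 0.18 and -0.29 before and 0.11 and -0.12 after), the ratio as a cause stays open. A change of DNA copy number may be a cause: a host gene's log2 fold change correlated with the mean of its 4 nearest neighbours (0.125 across 3008 genes, which are not independent replicates, against 0.0446 at the 95th percentile of 1000 permutations of positions, and 0.0674 against 0.0367 within chromosomes, with their medians removed), which met the bound fixed beforehand, but another split of the libraries gave 0.112 without that removal, a comparison made after the result, so it stays open. The 10 splits are too few for a share under 0.05 (real split 4 chromosomes, highest other 1, 1 of 10 with as many), and an effect of cadmium itself stays open too.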

How the results depend on the processing

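The 5 circRNAs that fell were the same 5 with other size factors, with library totals alone, without a filter, with DESeq2 and with limma, and a minimum count of 10 gave 7 that include them (1 rose and 6 fell). All 7 host genes were kept with other size factors, with library totals alone, with either other filter and among the 11 that DESeq2 called, while limma called 4, all among the 7. A 2-fold minimum left 3 circRNAs. Host genes numbered 2 without control replicates 1 and 3, with 1 shared. With the junction ratio as a covariate 3 circRNAs passed (1 shared), and 3 also without control replicates 1 and 3 (0 shared). The latter fit has 1 control library, assumed to vary like the cadmium libraries, so its counts do not separate the effect of that removal from what this library holds. With the other entry of the 2 doubled identifiers, chosen after seeing the data, 5 host genes passed, and PPP6R2 and ZCCHC2 did not (edgeR adjusted p = 0.0514 for both, against 0.0494). No named circRNA or gene that had been called reversed its sign. Leaving out each library in turn gave 0 to 13 circRNAs, 3 to 13 host genes, 1 to 5 chromosomes and 0 to 0 lists. It gave differences in detected circRNAs from -522.2 to -284.2 and in the exonic share of reads from 0.0896 to 0.205 percentage points. Chromosomes past the threshold numbered 0 with an estimated correlation, 2 with the junction ratio as a covariate and 2 without control replicates 1 and 3. The exonic share differed by 0.136 percentage points of reads and by 0.000822 of detected circRNAs. Of the circRNAs that the authors' deposited comparison lists, 506 pass unadjusted and 6 adjusted. The cause was not tested for these differences, except that fewer libraries were fitted where some were left out. The circRNAs called only with the covariate or without control replicates 1 and 3 each have a 0 listed in control replicate 2. Of the values of single circRNAs, genes, chromosomes and classes under the alternatives, 658 kept their direction and side of the threshold or their size, 77 were no longer past it and 8 came past it. The other 14 either changed sign without being past the threshold (circRNAs) or moved by more than the spread (libraries and classes). The covariate, the removal of control replicates 1 and 3 and the other alternatives named as such were chosen after seeing the data.

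The labels do not say whether equal replicate numbers pair the libraries. Correlations of deviations between libraries of the same number were 0.00900, 0.00389 and 0.0839. Between libraries of different numbers they ran from -0.0501 to 0.0402. These values are too few and too small to decide it. With the number as a replicate block 4 circRNAs, 6 host genes (2 rose and 4 fell), 4 chromosomes and 0 lists passed. All 4 circRNAs and 5 of the 6 host genes were among those called without it. The VAPA circRNA (edgeR adjusted p = 0.109), PPP6R2 (0.112) and ZCCHC2 (0.0613) did not pass. The median of 7 reads per circRNA limits what single circRNAs can show: in the simulated comparison 0 of 62 circRNAs changed by 1.5-fold were recovered.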

Other observations

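The tests on exon number, non-junction reads, zeros and the region of chromosome 2 were chosen only after the result was seen, as were the genes named in this part. Circles of a single exon took a larger share of junction reads with cadmium, 5.66% ± 0.112 against 4.87% ± 0.191 in controls (SD, n = 3 each, exact permutation p = 0.1, the smallest possible), higher in each cadmium library than in each control. This class holds the HIPK3 circRNA hsa_circ_0000284, with 1153, 0 and 537 reads in control replicates 1 to 3 and 948, 975 and 865 with cadmium. Its 0 in control replicate 2, where 448 reads were implied, adds to the difference. The share was not taken without this circRNA. Circles of 4 or more exons took 31.2% ± 1.18 and 32.8% ± 1.79 (SD, n = 3 each, exact permutation p = 0.3). Among host genes that did not pass the test, SNX6, a sorting nexin gene, had a log2 fold change of -1.16 and ATXN10 one of -0.45 (edgeR adjusted p = 0.186 for both). For MFF, a mitochondrial fission gene, 10, 8 and 8 reads were listed in control replicates 1 to 3 and 0 in each cadmium library (edgeR adjusted p = 0.186).

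Reads of the circRNA loci that do not cross the junction were tested per host gene in the same way. Of 2671 genes, SPAG16 fell (log2 fold change -2.07, SE 0.33, edgeR adjusted p = 0.0153) and 0 rose, with 362 at an unadjusted p under 0.05. With the junction ratio as a covariate 0 passed. ZDBF2, PTPRG and VAPA had -1.59, -1.28 and -1.06 without passing (edgeR adjusted p = 0.115 for ZDBF2, 0.146 for PTPRG and VAPA). NOX4, an NADPH oxidase gene, had -2.18 in these reads (edgeR adjusted p = 0.113) and -0.35 in junction reads. Across 2551 genes, which are not independent replicates, the log2 fold changes of both kinds of reads correlated with Pearson's r of 0.240 and Spearman's rho of 0.254.

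Some zeros stand beside high counts. In 94 cases, 1 per circRNA, a library was listed at 0 where the other 2 libraries of its group imply 10 or more reads, and in 5 cases 50 or more. They numbered 8, 16 and 15 in control replicates 1 to 3 and 7, 14 and 34 in cadmium replicates 1 to 3. The HIPK3 circRNA hsa_circ_0000284 had 1153, 0 and 537 reads in controls, the FAT1 circRNA hsa_circ_0001461 had 247, 0 and 238 with cadmium, and the CREBBP circRNA hsa_circ_0007637 had 0, 93 and 108 with cadmium. Without these 94 circRNAs the edgeR calls were the same 5 circRNAs and 7 host genes. The only circRNAs called higher without control replicates 1 and 3 were that of HIPK3, hsa_circ_0006114 of PTPRM (40, 0 and 50 reads in controls) and hsa_circ_0008192 of PTBP3 (65, 0 and 53 reads in controls), each with its 0 in control replicate 2, the only control library left in that fit.

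A loss of DNA over the shared region of chromosome 2 may be a cause of the lower SPAG16 and ZDBF2 circRNAs, as a hypothesis. The 19 other host genes between 200 and 220 Mb had a median log2 fold change of -0.37 (bootstrap 95% interval -0.75 to -0.06). The interval holds the bound of -0.50 that was set as 50% of the ZDBF2 value. It was drawn by resampling these genes, which are not independent replicates, so it does not measure the spread between libraries. Of 2594 windows with as many neighbouring host genes, which overlap one another, 84 (3.24%) had a median as low. Of the host genes nearest to the pair, PIKFYVE between them had 0.01 (SE 0.23), which goes against 1 continuous loss, while CREB1 between them had -0.73 (SE 0.42). NDUFS1, outside the pair beside ZDBF2, had -0.05 (SE 0.20). The hypothesis stays open, since these are single genes and the interval includes both a clear loss and almost none, and cadmium exposure itself was not separated from other differences between the cultures.

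The identifier hsa_circ_0006922 of ASXL1 stands for 2 entries of the annotation: one, used in the count table, had 19, 5 and 6 reads in controls, and the other had 541, 355 and 413.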
